A study of Rattus norvegicus with 6 samples.

How the data were processed

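Total RNA from the renal cortex of 6 male Sprague-Dawley rats was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. The rats were 5 weeks old at purchase, and 3 received corn oil and 3 received 2-amino-4-nitrophenol at 750 mg/kg/day for 4 weeks; the labels call the animals of a group biological replicates. The scanner files hold 62976 spots per array, of which 61657 are non-control probes with unique names. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, and the submitters' processing notes name version 10.7. Per the file headers, the deposited processed intensity is background-subtracted and detrended by the scanner software and on a linear scale, and the deposited flags mark probes that are well above background, saturated or outliers. The authors' value table holds, as a deposited ratio, each intensity divided by the 75th percentile of its array: its columns have a 75th percentile of 1.00 and medians of 0.107, 0.105 and 0.106 (corn oil) and 0.103, 0.103 and 0.106 (treated). Its scale and centring were settled by comparison with the scanner values, and 36961 probes were compared. Each column matched the scanner file of another replicate of its own group (SD of the log2 difference 0.0003 or 0.0004, against 0.293 to 0.500 for the scanner file of the same number), so replicate numbers follow the scanner files throughout.

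The log2 of the processed intensity, minus the array's 75th percentile over non-control probes, was used in the comparison. Probes flagged as outliers on any array (64) were left out, and probes well above background on all 3 arrays of at least 1 group were kept (40894). Genes were named only through the RefSeq accession of the probe and a RefSeq gene table of the GRCr8 assembly: 33356 probes carry such an accession, 27460 probes (44.5%) were named, for 15284 genes, and 34197 had no name here and were tested apart. No coordinates are given, since the array's annotation names no such build. Each gene was represented by its kept probe with the highest mean signal. The 2 groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 without a block, and p was adjusted by the Benjamini-Hochberg method over 11748 genes, with a threshold of 0.05. The prior degrees of freedom were 2.21 beside 4 residual degrees of freedom. Standard errors of single genes are those of limma. Those of list medians are taken over the member genes, and that of the erythroid ratio comes from the variance over the 3 arrays of each group. Gene-level values in the text are log2 values relative to the 75th percentile.

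Gene lists were compared with limma's camera at a preset correlation of 0.01, with adjustment over 39 lists (21 of functions and 18 of cell types) that have at least 3 measured genes. Of these, 8 passed (5 higher, 3 lower). With an estimated correlation 0 of the 8 calls held, and the directional test of fry gave 0. The mixed test of fry, for change in either direction, was not used for calls. It gave an adjusted p of 0.0145 for NRF2 target genes and 0.0561 for oxidative phosphorylation genes. Some lists that camera did not call passed it too, such as endothelium (0.0066). Camera sets the members of a list against all other genes, so higher and lower in its calls are relative to those. The median log2 change over all genes tested was 0.04, so a list with a small positive median can be tested as lower. The count adjusted over the list alone applies the Benjamini-Hochberg method to the members of that list. The lists, the tests and the rule for named genes were set before the data were examined. The rule takes up to 6 genes with the largest increase and 6 with the largest decrease among those past the threshold whose arrays do not overlap and that are well above background on all 6 arrays, the 2 members with the lowest p of each of the 10 lists with the lowest p, and 10 fixed genes whatever their values. At most 4 genes not well above background in 1 group were to be given as bounds, and 0 met that rule. Some genes that the rule takes are not reported here.

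The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, scaling on spike-in controls (7 probes), the authors' value table, no filter or a filter on all 6 arrays, a replicate block, a slide block, the mean over probes, eBayes with trend and robust settings, array weights, other thresholds, an estimated correlation, fry, and leaving out each array. Normexp was planned on mean signals and was run on median signals, which the scanner files hold, so that it counts as chosen after seeing the data, as do a threshold of 0.1 and the trend and robust settings taken singly. Scan date was not run as a block because it does not part the arrays otherwise than the slide does. The default estimate of array weights did not converge, and the gene-by-gene estimate was used.

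The comparison was tested on simulated data drawn around the real means and spreads of the 11748 genes, with 200 genes changed. Of 50 genes changed by each size, 20 were recovered at 1.5-fold, 34 at 2-fold, 46 at 4-fold and 48 at 8-fold, with 12 false calls. The changed genes were picked at random and had the same spread in both groups. These rates need not hold for genes whose spread differs between the groups, such as Nqo1 (SD 0.45 on corn oil and 1.52 on treated arrays). The adjusted p of a gene also depends on how many others pass. In the simulation 148 of the 200 changed genes passed, against 3 genes in the real data. The rates can therefore overstate what the real comparison recovers. Slc22a7, at 5.23-fold with an SD of 0.37 in both groups, had an adjusted p of 0.0799 in limma. A shift of 0.5 in the 25 NRF2 target genes was recovered, with 0 other lists called. The noise was drawn independently for each gene, whereas the estimated correlation within the NRF2 list was 0.348 in the real data. The simulation therefore cannot show how often camera at the preset calls lists of correlated genes. Plots were made with Python 3.11.15 and matplotlib 3.10.9.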

Results

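Gene expression was measured in the renal cortex of 6 male Sprague-Dawley rats, with 1 single-colour oligonucleotide array per animal. Of these rats, 3 had received corn oil and 3 had received 2-amino-4-nitrophenol, a nitroaromatic amine used in hair dyes, at 750 mg/kg/day, each for 4 weeks. The comparison asks which renal cortex transcripts differed between the dosed rats and the corn oil rats. Between 41986 and 43724 of the 61657 non-control probes (68.1% to 70.9%) were well above background on the corn oil arrays, against 37990 to 40848 (61.6% to 66.3%) on the treated arrays. No probe was saturated. Before scaling, the 75th percentile of the processed signal was 743 to 852 on the corn oil arrays and 564 to 685 on the treated arrays. The number of arrays, 3 per group, limits the precision of every value.

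On the first principal component, which held 40.2% of the variance, the corn oil arrays lay at -15.6, -21.3 and -19.1 and the treated arrays at 2.3, 30.4 and 23.3. On the second, with 24.9% of the variance, the treated arrays were spread from -29.8 (replicate 1) through -10.1 (replicate 3) to 21.5 (replicate 2), whereas the corn oil arrays lay between 4.7 and 8.0. The treated animals therefore differed more from each other than the corn oil animals did on these 2 components. All 3 treated arrays and corn oil replicates 1 and 3 shared a slide, on which the corn oil arrays occupied the first row and the treated arrays the second row. Corn oil replicate 2 lay on another slide, in the second row. As it was the only array there, the slide block below and the fit without corn oil replicate 2 are a single check and give the same log2 changes.

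NRF2 target genes, which encode enzymes of glutathione synthesis, quinone reduction and conjugation, were higher in the treated renal cortex. The 25 measured members rose as a set, with a median log2 change of 1.04 (limma camera, adjusted p = 2.26e-08; adjusted p = 0.655 with an estimated correlation). Relative to each gene's corn oil mean, the median over the members was 1.36, 0.45 and 1.27 on treated replicates 1, 2 and 3, against -0.01, -0.11 and 0.09 on the corn oil arrays. Gclc, the catalytic subunit of glutamate-cysteine ligase, had a log2 change of 1.63 ± 0.23 (SE, n = 3 per group; 3.09-fold). Osgin1, an oxidative stress response gene, had a log2 change of 1.39 ± 0.21, and Nqo1, a quinone reductase, of 3.44 ± 0.74 (10.9-fold). The log2 values of Nqo1 were 1.53, -1.35 and 0.90 on treated replicates 1, 2 and 3, against -2.58, -3.18 and -3.47 on the corn oil arrays. Adjusted over the list alone, 16 of the 25 members passed, all of them higher, while 0 passed over all genes tested; the adjusted p over all genes was 0.0805 for Gclc, 0.0867 for Osgin1 and 0.122 for Nqo1. The glutathione transferases Gstm1 (4.43 ± 0.94) and Gstp1 (2.74 ± 0.43) were chosen after their values were seen, and cross-hybridisation between their close paralogs was not assessed. Hmox1, the inducible heme oxygenase, did not pass, at 0.55 ± 1.04: corn oil replicate 3 had a log2 value of 2.00, against -1.57 and -1.42 on the other corn oil arrays. The count of 16 fell to 7 without corn oil replicate 1, 7 after quantile normalization and 7 after scaling on spike-in controls, and was 21 at the highest, with array weights. With the slide as a block the median was 1.00 and the count 11 (9 without corn oil replicate 2).

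**Figure D1:**
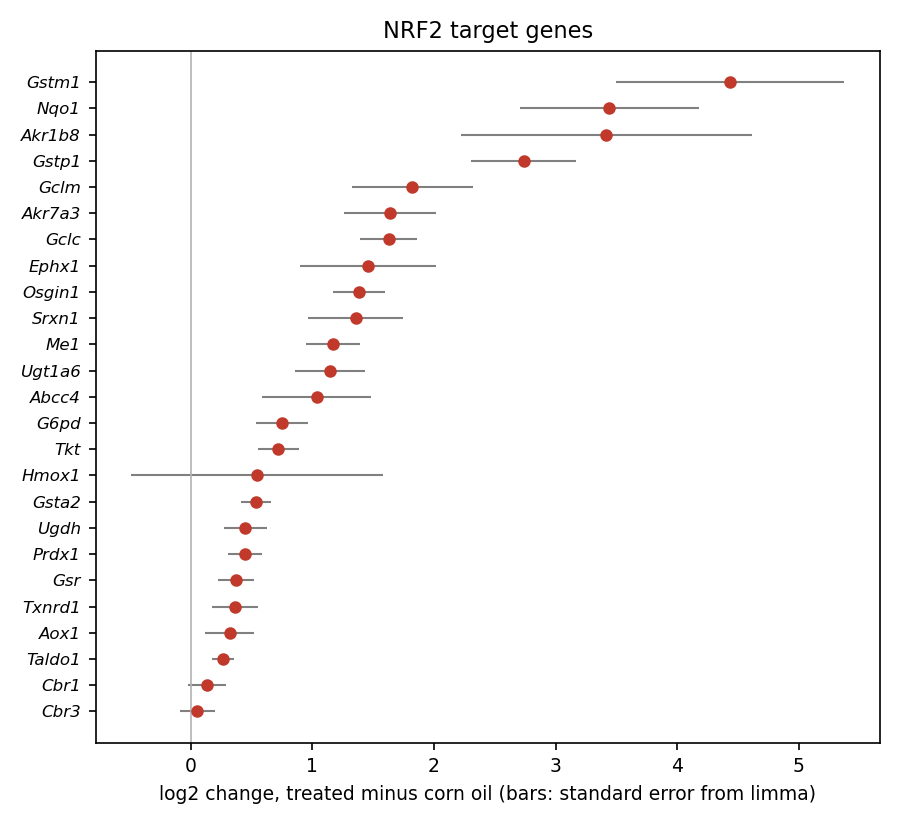
Log2 change (treated minus corn oil, 3 arrays per group) of each of the 25 measured NRF2 target genes on the horizontal axis, with 1 gene per line; points are estimates and bars are standard errors from limma. Every point lies above 0, from 0.06 for Cbr3 to 4.43 for Gstm1, and the bars of Cbr1, Cbr3 and Hmox1 cross 0.

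Single genes reached the threshold rarely. Hes1, a transcriptional repressor downstream of Notch, rose by 1.15 ± 0.08 on the log2 scale, and Ropn1, which encodes the sperm flagellum protein ropporin, rose by 1.37 ± 0.10. Cemip2, a cell surface protein linked to hyaluronan breakdown, fell by 1.14 on the log2 scale (SE 0.09). Each had an adjusted p of 0.0345 (limma), and for each the 3 treated arrays lay outside the range of the 3 corn oil arrays. The other probe of Hes1 disagreed in direction (-0.13), the other probe of Cemip2 gave -0.28, and the other probe of Ropn1 gave 1.28. These were the 3 of 11748 tested genes that passed, 2 higher and 1 lower. At an unadjusted p under 0.05 there were 2535 genes, 1679 higher and 856 lower. The arrays of both groups did not overlap for 3549 genes, 30.2% of those tested, where chance gives 10% for a single gene. Genes vary together, so the share in 1 split can lie far from 10% by chance, and it was not computed for the other splits. With the slide as a block, the log2 changes were 1.12 for Hes1, 1.42 for Ropn1 and -1.19 for Cemip2. Among 20549 tested probes without a gene name, 0 passed in limma.

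The count of called genes depended on single arrays and on the model, and of the 39 gene lists 8 passed at the preset correlation and 0 with an estimated one. At the preset, 6 of the 10 splits of the 6 arrays into groups of 3, the real split included, gave at least 8 lists. The highest gave 13, so that a set call at the preset does not by itself set the treated arrays apart. In limma no gene passed without corn oil replicate 1, 2 or 3 (1745, 1761 and 1546 genes at an unadjusted p under 0.05), nor with the slide as a block (1764 genes). By contrast, 74 passed without treated replicate 2 (57 higher, 17 lower), 14 without treated replicate 1 (3 higher, 11 lower) and 4 without treated replicate 3 (4 higher, 0 lower). Genes lower in treated cortex made up 33.8% of the genes at an unadjusted p under 0.05, but 53.7% after quantile normalization, 22.1% after normexp background correction and 95.3% after spike-in scaling, which shifted the median log2 change of all genes by -0.32.

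Fatty acid oxidation and peroxisome genes passed as lower in the treated renal cortex at the preset correlation only. The 27 measured members fell as a set (limma camera, median log2 change -0.22, adjusted p = 0.000127; adjusted p = 0.655 with an estimated correlation), and the median was -0.058, -0.23 and -0.34 on treated replicates 1, 2 and 3, against -0.053, 0.030 and -0.022 on the corn oil arrays. Hadhb, a subunit of the mitochondrial trifunctional protein, had a log2 change of -0.34 ± 0.08 (adjusted p = 0.130). Adjusted over the list alone, 8 members were lower and 0 higher, and over all genes tested 0 passed. The 8 fell to 1 without corn oil replicate 3 or treated replicate 3 and with the slide as a block, and increased to 16 after quantile normalization, where the median was -0.35. With the slide as a block, the median was -0.19.

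Oxidative phosphorylation genes, which encode subunits of the respiratory chain and ATP synthase, were higher as a set by a median log2 change of 0.33 over 28 members (limma camera, adjusted p = 6.99e-07; adjusted p = 0.655 with an estimated correlation). Atp5pb, an ATP synthase subunit, had a log2 change of 0.41 ± 0.09. Adjusted over the list alone 0 of the 28 members passed, although 24 did without treated replicate 1, 23 with array weights and 20 with the trend setting. Over all genes tested, the median log2 change went from -0.12 in the 10% of genes with the lowest mean signal to 0.23 in the 10% with the highest. After quantile normalization the list's median was 0.05 and it no longer passed. After spike-in scaling the median was 0.0070, and the list still passed as higher than the other genes. With the slide as a block it was 0.31. Cholesterol synthesis genes were also higher as a set, by a median of 0.23 over 19 members (adjusted p = 0.0309; adjusted p = 0.670 with an estimated correlation). Dhcr7, which makes cholesterol from its immediate precursor, had a log2 change of 0.62 ± 0.11 and was the 1 member that passed adjusted over the list alone. Sqle, squalene epoxidase, had 0.50 ± 0.18. With the slide as a block the changes were 0.68 for Dhcr7 and 0.33 for Sqle. The cholesterol call was lost with the slide as a block (median 0.16), without treated replicate 3, after normexp correction and with no filter on dim probes. After spike-in scaling the cholesterol median was -0.09, and the list still passed as higher than the other genes.

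**Figure D2:**
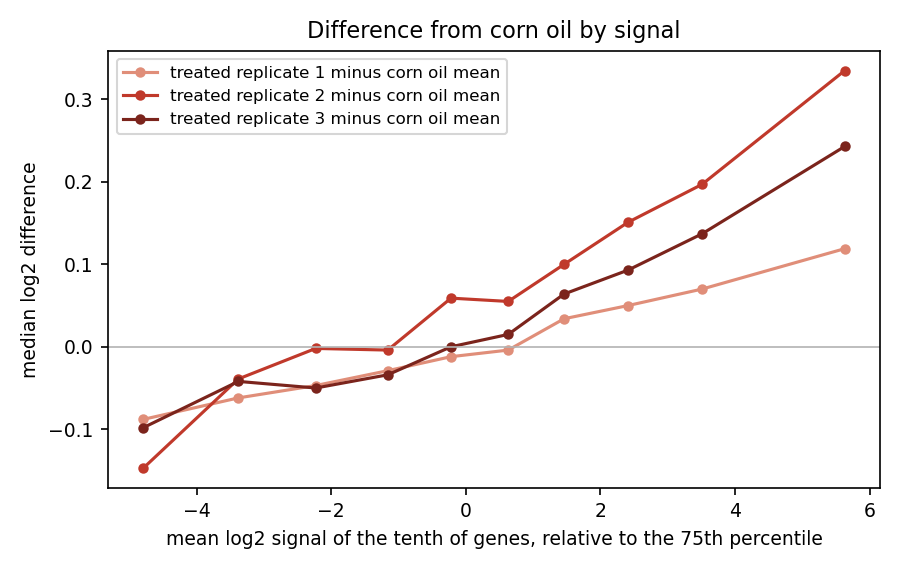
Median log2 difference of each treated array from the corn oil mean (vertical axis) for 10 equal bins of genes ordered by mean log2 signal relative to the 75th percentile (horizontal axis); 1 line per treated replicate. All 3 lines climb with signal, to 0.12, 0.34 and 0.24 in the brightest bin for replicates 1, 2 and 3.

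Among markers of nephron segments, 3 lists passed. Markers of the proximal straight tubule (the S3 segment) rose as a set, by a median log2 change of 0.34 over 5 members (limma camera, adjusted p = 0.00910; adjusted p = 0.655 with an estimated correlation). Slc22a7, an organic anion transporter, had a log2 change of 2.39 ± 0.25 (5.23-fold) and Slc7a13, an amino acid transporter, of 1.21 ± 0.27, and these 2 passed adjusted over the list alone, 4 without treated replicate 2. Markers of the distal convoluted and connecting tubule fell as a set, with a median of -0.37 over 6 members (adjusted p = 0.0211; adjusted p = 0.655 with an estimated correlation). The thiazide-sensitive cotransporter Slc12a3 had a log2 change of -0.53 ± 0.16 and the sodium-calcium exchanger Slc8a1 of -1.19 ± 0.36. These were the largest changes among their kept probes, of which the smallest were -0.13 for Slc12a3 (3 probes) and -0.44 for Slc8a1 (4 probes). Of the distal markers, 3 passed adjusted over the list alone, but 0 did without any 1 corn oil array, without treated replicate 2 or 3, with the slide as a block, with no filter on dim probes or with the mean over probes. Markers of the collecting duct principal cell fell as a set, with a median of -0.25 over 10 members (adjusted p = 0.0151; adjusted p = 0.655 with an estimated correlation). Hsd11b2, which inactivates glucocorticoids in aldosterone target cells, had -0.39 ± 0.10 and the sodium channel subunit Scnn1g -0.45 ± 0.15, and 0 members passed adjusted over the list alone. Of its members, 3 were lower without treated replicate 1, 2 without treated replicate 2, 4 after normexp correction, 3 after quantile normalization and 5 after spike-in scaling. The lower count was 2 with the mean over probes, 1 with the trend setting, 4 with trend and robust settings and 5 with array weights. With the slide as a block, the medians were 0.47 for S3, -0.29 for distal and -0.21 for collecting duct markers. The set calls were lost without treated replicate 1 for the S3 markers, without treated replicate 3 for the collecting duct markers, and with the slide as a block or without treated replicate 3 for the distal markers.

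Genes of the ER stress and amino acid response rose as a set, by a median log2 change of 0.23 over 20 members (limma camera, adjusted p = 0.0151; adjusted p = 0.655 with an estimated correlation). Asns, asparagine synthetase, had a log2 change of 1.61 ± 0.20 (3.06-fold; adjusted p = 0.0799) and the transcription factor Atf5 of 0.82 ± 0.16. Asns, Atf5 and the transcription factor Atf3 (0.78 ± 0.17) were the 3 members that passed adjusted over the list alone, whereas the chaperones Hspa5 (0.17 ± 0.11), Hsp90b1 (-0.19 ± 0.16) and Calr (0.01 ± 0.09) did not; Atf3 and the chaperones were chosen after their values were seen. The median was 0.29 with the slide as a block. The count was 1 without corn oil replicate 1 or 3, 7 without treated replicate 1, 5 without treated replicate 2 and 12 with array weights. The set call was lost without corn oil replicate 1, after normexp correction, after quantile normalization and with no filter on dim probes. After spike-in scaling the median was -0.09, and the set still passed as higher than the other genes.

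Erythroid markers had the largest list median, 1.15 over 5 members, but missed the threshold (limma camera, adjusted p = 0.0578; adjusted p = 0.655 with an estimated correlation). The beta globin gene Hbb had a log2 change of 0.96 ± 0.19, and Ahsp, the chaperone of free alpha globin, of 2.15 ± 0.46. Adjusted over the list alone, 4 of the 5 passed (Hbb, Hbb-b1, Ahsp and Alas2), all higher, and 1 after spike-in scaling. The median was 0.97 with the slide as a block, and the set passed without corn oil replicate 1 or 3, without treated replicate 2 or 3, after quantile normalization or spike-in scaling, with the mean over probes, with the trend setting and with the replicate block (adjusted p = 0.01173). Iron and heme handling genes had a median of 0.29 over 14 members (-0.025 after spike-in scaling) and did not pass (adjusted p = 0.0885). Biliverdin reductase Blvrb had a log2 change of 0.83 ± 0.10 (adjusted p = 0.0799) and the endocytic receptor Lrp1 of -0.44 ± 0.11 (-0.17 from its other probe). Adjusted over the list alone 3 members were higher and 1 lower. The median was 0.23 with the slide as a block. The higher count was 1 with that block or without any 1 treated array, and the set passed as higher without treated replicate 2, with the mean over probes, with array weights and, relative to the other genes, with spike-in scaling.

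**Figure D3:**
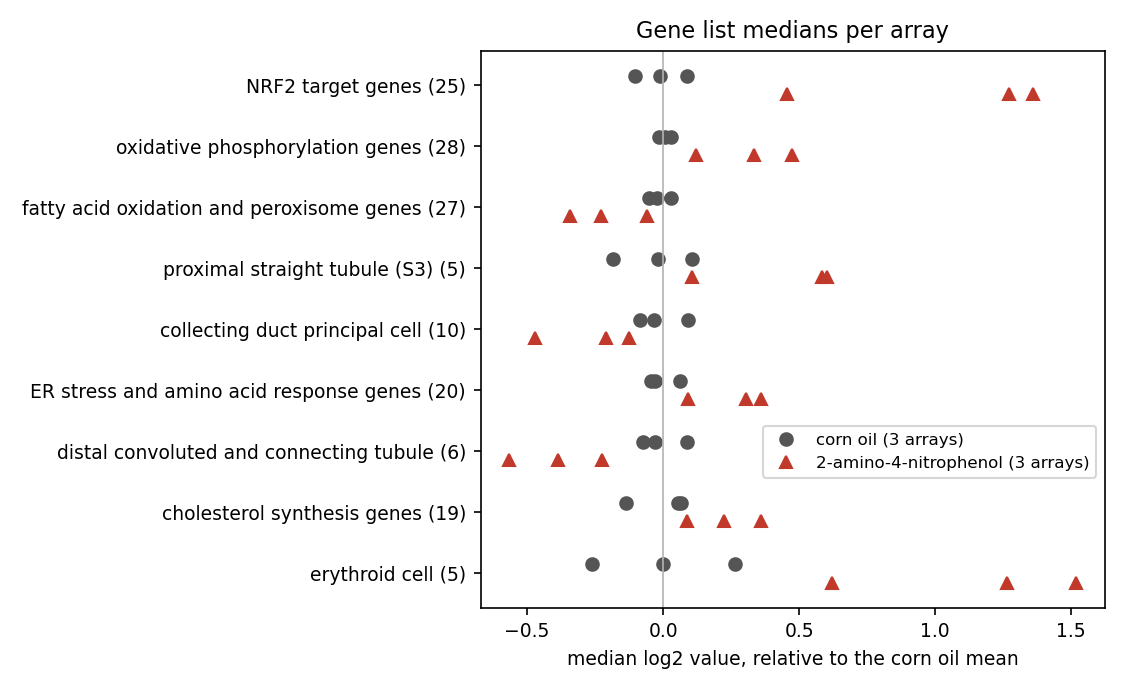
Median log2 value of the genes of each list, relative to each gene's corn oil mean (horizontal axis), for the 9 lists with the lowest camera p (number of measured genes in brackets); grey circles are the 3 corn oil arrays and red triangles the 3 treated arrays. The treated arrays lie outside the corn oil arrays for each of the 9 lists, by the smallest margin for the S3 markers, where treated replicate 2 (0.107) lay just above corn oil replicate 2 (0.106). The 9 lists were picked by p from these same arrays, so this is no separate support. Some lists that did not pass were parted in the same way, among them glycolysis genes and podocyte markers.

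Markers of tubular injury did not pass as a set (median log2 change 0.13 over 18 members, camera adjusted p = 0.408), and 1, Krt19, passed as higher adjusted over the list alone (2.84-fold; adjusted p = 0.0810 over all genes; named after its value was seen). Among them Lcn2, the injury marker NGAL, had a log2 change of 0.81 ± 0.84, Clu (clusterin) -0.61 ± 0.23 and Spp1 (osteopontin) 0.11 ± 0.36, and none of these passed. The sign for Lcn2 rested on corn oil replicate 3, with a log2 value of -4.68 against -1.44 and -1.75 on the other corn oil arrays; without it the change was -0.21. Havcr1, which encodes kidney injury molecule KIM-1, was well above background on 2 corn oil and 2 treated arrays and was not tested. Cyp1a1, the classical target of the aryl hydrocarbon receptor, was not well above background on any array. AhR target genes had a median of 0.70 over 4 members (adjusted p = 0.153), and passed without treated replicate 2 and after spike-in scaling. The 2 members that were higher adjusted over the list alone, Nqo1 and Ugt1a6, are also on the NRF2 list, while Ahrr (-0.22 ± 0.36) and Aldh3a1 (0.25 ± 0.13) did not pass; the members were named after their values were seen. The p53 target Cdkn1a had 0.46 ± 0.15 from its brighter probe and -0.55 from the other, and p53 target genes as a set had a median of 0.11 (adjusted p = 0.687). Umod, which encodes uromodulin of the thick ascending limb, had 0.45 ± 0.12, and the phosphate transporter Slc34a1 of the proximal tubule 0.19 ± 0.08. Neither passed, and Slc34a1 was 0.01 from its other probe and -0.15 after quantile normalization.

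The other lists did not pass either, with adjusted p from 0.138 to 0.900 in limma camera. Cell division genes had a median of 0.45, with 1.09 on treated replicate 2 against -0.02 and 0.14 on treated replicates 1 and 3. Their corn oil medians were 0.32, -0.51 and 0.16 on replicates 1, 2 and 3. With the slide as a block the median log2 change was 0.16. Fibroblast markers likewise had 0.87 on treated replicate 2, -0.31 on replicate 1 and 0.28 on replicate 3, with a median log2 change of 0.26 (0.14 with the slide as a block). On corn oil replicates 1, 2 and 3 they had 0.11, -0.15 and 0.03. Medians were -0.22 for vitamin D, phosphate and calcium genes, 0.18 for organic ion and drug transporters (2 members higher and 1 lower adjusted over the list alone), 0.12 for glycolysis, 0.12 for gluconeogenesis, 0.05 for amino acid metabolism (3 higher adjusted over the list alone) and 0.06 for heat shock and metallothionein genes. Immune and matrix lists had medians of -0.04 for extracellular matrix and fibrosis genes, 0.12 for chemokine and NF-kB genes, 0.12 for complement and acute phase genes (1 lower adjusted over the list alone), 0.09 for interferon and antigen presentation genes, 0.15 for macrophage, -0.29 for T and NK cell (these passed as lower with the slide as a block, median -0.49), 0.25 for B and plasma cell (1 higher adjusted over the list alone) and 0.00 for neutrophil markers. Among the remaining cell types, medians were -0.02 for proximal tubule (1 higher and 1 lower adjusted over the list alone), 0.14 for thick ascending limb, 0.02 for intercalated cell, -0.05 for podocyte, 0.05 for smooth muscle, pericyte and mesangium (1 higher adjusted over the list alone), 0.44 for adipocyte and 0.11 for adrenal gland markers. Some of these lists passed under other settings: proximal tubule markers as lower after quantile normalization (median -0.29), vitamin D, phosphate and calcium genes as lower after quantile normalization, normexp correction and with the mean over probes, and cell division genes as higher after quantile normalization, after spike-in scaling and without corn oil replicate 1 or 3 or treated replicate 3. Without treated replicate 2, organic ion and drug transporters passed as higher and extracellular matrix and fibrosis genes as lower. After spike-in scaling, transporters (median -0.14), fibroblast (-0.06) and adipocyte markers (0.12) passed only as higher than the other genes, since the median of all genes was then -0.28. The median, the mean and the test did not agree in sign for intercalated cell markers (median 0.02, mean 0.03, tested lower), for endothelium (median 0.05, mean -0.03, tested lower; 1 lower adjusted over the list alone), for medulla, papilla and urothelium (0.02, -0.08, lower) and for renin-angiotensin-aldosterone genes (-0.12, 0.05, lower; 2 higher and 1 lower adjusted over the list alone).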

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

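Normexp correction, the threshold of 0.1 and the trend setting alone were chosen after seeing the data. The count of 3 genes past the threshold was also 3 with median scaling, the authors' value table, the filter on all 6 arrays and the robust setting, and 4 with quantile normalization. It was 56 with normexp correction, 69 with the trend and robust settings, 24 with trend alone, 2010 with array weights and 132 at an adjusted p under 0.1. With spike-in scaling it was 9 (1 higher, 8 lower), and 0 of the 3 genes were among them. It was 0 at an adjusted p under 0.01, with no filter on dim probes, with the mean over a gene's probes and with the slide block, where limma gave 3496, 2443 and 1764 genes at an unadjusted p under 0.05 in the last 3. Leaving out 1 array gave 0 to 74 genes. The count of 8 lists was 15 with spike-in scaling, 0 with an estimated correlation and 0 with the directional test of fry. It was 7 to 13 when 1 array was left out (13 without treated replicate 2). The cause of these shifts was not tested. The replicate number used as a block gave 0 genes (2121 at an unadjusted p under 0.05) and 9 lists; the correlations of same-numbered arrays were 0.006, -0.050 and -0.032, so that the samples share only a number and no pairing was assumed. Spike-in scaling shifted the log2 change of every gene by -0.32, so that any value between 0 and 0.32 turned by construction. Single genes and called lists changed sign as follows: Cdkn1a with the mean over probes (-0.043), Hmox1 without corn oil replicate 1 (-0.074; 1.71 at the highest, without corn oil replicate 3), Lcn2 without corn oil replicate 3 (-0.21; 1.40 without corn oil replicate 1 and 1.41 with array weights), Slc34a1 with quantile normalization (-0.15) and spike-in scaling (-0.12), and under spike-in scaling the medians of ER stress and amino acid response genes (-0.089) and cholesterol synthesis genes (-0.090). Spp1 was -0.0078 with quantile normalization, -0.21 with spike-in scaling, -0.074 with the slide block or, which is the same check, without corn oil replicate 2, -0.36 with array weights, and -0.078, -0.050 and 0.46 without treated replicates 1, 2 and 3. Among lists that were not called, 6 medians changed sign with quantile normalization, 6 with normexp correction and at most 4 in each other setting except spike-in scaling. Signal near background left Havcr1 untested, with 2 arrays per group well above background.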

Other observations

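The tests of slide row, of signal strength, of proximal tubule and S3 share and of the count of genes at an unadjusted p under 0.05 were chosen only after the results were seen, and so were the genes in the next 3 sentences. Among the 132 genes at an adjusted p under 0.1 in limma (87 higher, 45 lower), 26 changed at least 2-fold without overlap between the groups and were well above background on all 6 arrays, 21 higher and 5 lower, of which 3 pass 0.05. Areg, the EGF receptor ligand amphiregulin, had the largest difference of the 26, at 4.19 ± 0.62 (SE, 18.2-fold; adjusted p = 0.0810), followed by Gstp1, Slc22a7, Htatip2 (1.96 ± 0.31) and Mep1b, a brush border metalloprotease (1.92 ± 0.22). The organic anion transporter family member Slc22a24 (1.74 ± 0.29), the esterase Aadac (1.56 ± 0.22) and the keratin Krt19 (2.84-fold) were higher too, while Mylk3 (-1.51 ± 0.20), Lhfpl2 (-1.16 ± 0.19) and Reln (-1.07 ± 0.15) were lower.

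The lower values of Pdk4 (-0.97 ± 0.23), Ehhadh (-0.92 ± 0.24) and Cyp4a1 (-0.62 ± 0.17), chosen after they were seen and among the 8 of 27 members lower adjusted over the list alone (0 over all genes tested), raise the hypothesis that targets of PPARa, the receptor that induces fatty acid oxidation, were lower in general. A second list of PPARa targets, none of them in the first, was fixed before it was tested, and 13 of its genes were measured. Their median log2 change was -0.20, 10 were lower and 3 higher, and 4 were lower adjusted over the list alone: Angptl4 (-0.997 ± 0.188), Creb3l3 (-1.72 ± 0.36), Vnn1 (-1.07 ± 0.23) and Retsat (-0.34 ± 0.08). The camera p was 0.000341 with the preset correlation and 0.177 with an estimated one, so this may reflect lower PPARa activity only as far as the preset holds. A smaller share of proximal tubule cells was not tested for these genes. The median of the proximal tubule markers was -0.02 in the main setting. After quantile normalization they passed as lower with a median of -0.29, where the first fatty acid list had -0.35.

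The higher Asns, Atf5 and Atf3 raise the hypothesis that targets of ATF4, the transcription factor of the amino acid response, were higher. The other members of that response on the same list did not pass adjusted over it: Trib3 (1.00 ± 0.30), Ddit3 (0.47 ± 0.16), Atf4 (0.44 ± 0.17), Phgdh (0.11 ± 0.11), Psat1 (0.11 ± 0.17) and Chac1 (0.063 ± 0.132). In a second list fixed before its test, 15 genes were measured, with a median log2 change of 0.22, 12 higher and 3 lower. Adjusted over the list alone 2 were higher: Mthfd2, a mitochondrial folate enzyme (1.44 ± 0.33), and the aminotransferase Gpt2 (1.07 ± 0.24). The camera p was 0.0328 with the preset correlation and 0.228 with an estimated one, so this may reflect ATF4 only as far as the preset holds.

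The rise of oxidative phosphorylation genes could come from the trend of change with signal strength. Its median of 0.33 lay at the 94.6th percentile of 10000 random lists matched on mean signal, whose own median was 0.26, and it fell to 0.05 with quantile normalization. The proximal tubule markers did not rise as a set: their median was -0.0199 ± 0.0903, at the 0.01th percentile of their matched lists, whose median was 0.23. This was more than 2 SE below even a rise 50% as large as that of the list, though barely so. The SE is taken over the 18 markers and holds no variation between animals, and the rule was changed after its value was seen. The test therefore cannot decide on a larger share of proximal tubule cells. A larger share of S3 cells alone stays open too. The median of the 5 S3 markers was 0.34 ± 0.51 (SE over the markers), at the 96.5th percentile of their matched lists. After quantile normalization it was 0.35 and the S3 list still passed at the preset correlation (limma camera, adjusted p = 0.0196). It did not fall there as the oxidative phosphorylation median did. For the oxidative phosphorylation genes, the tests of signal strength showed no rise beyond the trend. Whether the treatment itself underlies the trend stays open and was not tested.

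For the NRF2 target genes, the same trend is argued against: their median of 1.04 lay at the 100th percentile of the matched random lists, whose median was 0.13, and the list passed after quantile normalization. A larger share of proximal tubule cells is argued against too, as it would have raised the proximal tubule markers by a like amount. Their median change was -0.0199 ± 0.0903 (SE over the markers). Per array it was -0.01, 0.11 and -0.03 on treated replicates 1, 2 and 3, against 1.36, 0.45 and 1.27 for the NRF2 list. A larger share of S3 cells stays open (0.34 ± 0.51 for their markers). The row on the slide cannot be told apart from the treatment, because 1 corn oil array alone lay in the second row; it stood at -0.342 on a scale from 0 (the first-row corn oil arrays) to 1 (the lowest treated array). Activation of NRF2 by the treatment is a hypothesis beside these open points and was not tested apart from the group difference.

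The higher erythroid markers may reflect more blood in the treated tissue or a larger share of young red cells. Blood of unchanged makeup would raise all markers alike, and Ahsp and Alas2 changed relative to Hbb and Hbb-b1 by 0.736 ± 0.373 (SE over arrays, log2). Per array this ratio was -6.24, -7.30 and -7.27 on the treated and -7.87, -7.43 and -7.73 on the corn oil arrays. The 2 explanations cannot be told apart, since the difference rests mostly on treated replicate 1.

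With 6 arrays there are 10 splits into groups of 3, too few for a share under 0.05. The real split gave 3 genes past the threshold and the highest of the others 2, so 1 of the 10 gave as many. At an unadjusted p under 0.05 the real split gave 2535 genes and the highest other 683, again 1 of 10. Each other split mixes arrays of both groups, so any real difference widens its within-group spread and can lower its gene count. The other splits are therefore no reference without a difference. For gene lists the real split gave 8 and the highest other 13, and 6 of the 10 splits gave as many as the real one.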
